A study of Mus musculus with 4 samples.

How the data were processed

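The 4 libraries were of hepatic nonparenchymal cells from 1 control, 1 TAA, 1 TAA+C7.5 and 1 TAA+C30 mouse. Per the labels' protocols, livers were dissociated enzymatically, red cells were lysed, most hepatocytes were removed by a low-speed spin, and droplet libraries were made from the 3 prime end of transcripts. The deposited matrices hold UMI counts per gene and barcode, whole numbers that the authors made with Cell Ranger 3.1.0, per the file headers, on genome build mm10, per the labels. Cell calling settings and the gene annotation are not stated. The same counts in dense text tables, compared value by value, were not used. The files list 55450 genes, of which all IDs were found in GENCODE M21 (GRCm38, the same build as mm10), from which 1-based coordinates were taken; 31176 genes had a UMI and 108 symbols were listed more than once.

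Barcodes with under 200 genes (117, 210, 10 and 59) or with over 20% of UMIs from mitochondrial genes (678, 193, 24 and 47) were removed. Doublets were called per library with Scrublet in Scanpy 1.11.5, at an expected rate of 5%, and 120, 68, 126 and 114 barcodes were removed. The kept cells held 24725259, 47173225, 17259388 and 26641974 UMIs, and 738, 233, 673 and 472 of them had under 1000 UMIs. Cells of all libraries were clustered together after log normalisation: the 2000 most variable genes found in at least 10 cells, 30 principal components, 20 nearest neighbours and Leiden clustering at resolution 1 gave 31 clusters. No batch correction was applied, since library and group coincide.

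Clusters were named from fixed marker sets of 22 cell types. A cluster with markers of more than 1 type, low depth or mixed top genes was clustered again (15 neighbours, resolution 0.5, at least 60 cells), which gave 51 clusters. A name needed 3 markers at least 2-fold above other clusters and detected in 10% of cells, at least 20 cells, a second-best score under 0.75 of the best, and no more markers of another class than of its own among its 10 top genes. A cluster of low depth for its libraries also needed a marker of its class among those top genes. These naming thresholds and the second round were set after seeing the data, and 13 clusters stayed unnamed. In the Gpnmb-led macrophage cluster, markers of Kupffer cells and of macrophages were equally many among those top genes.

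Gene values are UMIs summed per library and class, as CPM of the class total, and compared as log2 ratios with 10 CPM added to both sides, in classes with at least 50 cells in both libraries. Ratios have exact conditional binomial intervals and sums exact Poisson intervals. Where a library had 0 UMIs, the fold was computed against 3 counts, without the counting error of the other library. No p-value was computed, since cells are not replicates.

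Comparisons were TAA against control, each dose against TAA and the higher against the lower dose. Gene lists, markers, filters, comparisons and 25 alternatives were chosen before the data were examined. Genes were named by a fixed rule: in each class with at least 100 cells in every library (5 classes), the 2 genes with the highest and the 2 with the lowest log2 ratio, among genes with at least 50 CPM and 30 UMIs in the higher library. Left out of it were mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, Xist and Y-linked genes, uncharacterised gene models, the hepatocyte list, and genes whose CPM was under 10% of that in another class of the same library. For lists, up to 2 members with the largest ratio in each direction served as examples, with Ptgs1 and Ptgs2 always eligible. The 10% limit was not applied to these examples. The share of T cells with Pdcd1, Tox and Gzmk was singled out after their values were seen.

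The 24 lists were sinusoidal identity, capillarization, periportal endothelial, pericentral endothelial, endothelial adhesion and vascular tone, Kupffer identity, lipid-associated or scar-associated macrophage, inflammatory cytokines and NF-kB targets, interferon response, MHC class II presentation, prostanoid and leukotriene metabolism, fibrillar matrix and myofibroblast, quiescent stellate, matrix proteases and inhibitors, TGF-beta targets, cytotoxic and effector lymphocyte, T cell exhaustion and regulation, naive T, B cell activation, cell cycle, oxidative stress and metallothionein, dissociation and immediate early response, hepatocyte free RNA and erythroid. Each was measured in the classes fixed for it, over members with at least 10 UMIs in both libraries together, where at least 5 were measured, which gave 153 medians over 23 lists. A median is given with its percentile among 10000 random lists of the same size matched on mean expression (within 100 genes by rank), as a description of these libraries. Ranges of medians come from 1000 Poisson redraws of the counts.

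For the return toward control, genes at least 2-fold different between control and a random set of the TAA cells were measured against the remaining TAA cells, over 20 splits, beside counts simulated with no difference. Mitochondrial, ribosomal protein, haemoglobin, hepatocyte and immunoglobulin genes were left out of it, a choice made after seeing the data.

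Alternatives covered the mitochondrial filter, doublets, clustering resolution, class assignment by marker scores, minimum depth, pseudocount, scaling (TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0, in R 4.3.3), low-count filters, weighting and thinning of cells, the genes in the total, and the size and cells used for the return. After seeing the data 6 more were added: shares of leukocytes, the haemoglobin-rich part counted as endothelial, the same weights in each library for clusters with at least 20 cells in all libraries compared (for lists, genes and the return), and all genes kept in the return.

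The gene ratios, list percentiles and return were tested on simulated data for T cells. Ratios and percentiles were drawn for TAA+C7.5 against TAA over 13011 genes, with 200 genes changed. Of 50 genes truly 2-fold higher 49 (98%), and of 50 truly at 0.5 of their level 45 (90%), were measured at least 1.5-fold apart in the right direction, as were all 50 each at 4-fold and 0.25. Of 12811 unchanged genes 0 were, and 96.3% of intervals held the true ratio. The changed genes were chosen among well counted genes of a large class. Simulated counts had Poisson spread alone, without differences in cell mix or between mice. The rates therefore do not cover rare classes, genes with few UMIs or the spread between mice. A list of 20 genes all 2-fold higher reached percentile 100 and an unchanged list 47.8. The return was simulated apart, for T cells of control, TAA and TAA+C7.5 over 55450 genes. A true return of 0.5 was measured as 0.448 over 179 genes and a true return of 0 as 0.00249 over 180 genes. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, python-igraph 0.11.9, Biopython 1.88 and matplotlib 3.10.9. Classes with under 50 cells in a library, such as endothelial cells of TAA+C30 and Kupffer cells of both celecoxib libraries, were left out of gene comparisons.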

Results

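Single-cell RNA sequencing was made on hepatic nonparenchymal cells of 4 wild-type C57B6 mice aged 18 to 20 weeks, with 1 droplet library per mouse and 1 mouse per group. The control mouse received saline. The TAA mouse received thioacetamide, a liver toxin that produces fibrosis, for 12 weeks. The TAA+C7.5 and TAA+C30 mice received thioacetamide and, from week 5, celecoxib at 7.5 and 30 mg/kg by mouth. Celecoxib inhibits cyclooxygenase-2, the prostaglandin-forming enzyme that Ptgs2 encodes. With a single mouse per group no difference had a replicate check, no test between groups was made, and each comparison is one between libraries. In the order control, TAA, lower dose and higher dose, which is kept throughout, the libraries held 6583, 6915, 6117 and 6284 barcodes with 26603317, 48419305, 17888247 and 27555592 unique molecular identifiers (UMIs). After filters 5668, 6444, 5957 and 6064 cells remained, with medians of 3363.5, 4553, 1971 and 3101.5 UMIs per cell. For a count of 0 cells a limit of 3 cells was taken, a share of 0.0529%, 0.0466%, 0.0504% and 0.0495%. Ranges in parentheses are exact 95% intervals (Clopper-Pearson for shares, Poisson or conditional binomial for UMIs) and cover counting error only.

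The cells fell into 15 named classes of leukocytes, endothelial cells, cholangiocytes and hepatocytes. The 13 clusters that could not be named, by thresholds set after seeing the data, held 8.84%, 3.57%, 1.11% and 1.60% of cells. The largest of them in control, with 359 cells there and 9, 2 and 0 in the other libraries, carried both haemoglobin and endothelial transcripts. Fibroblast and stellate cell markers were found together in a cluster of 27, 12, 10 and 16 cells, so that stellate cells formed no class and the quiescent stellate list gave no value. When each cell was instead assigned to its best-scoring marker set, 87.0% kept their class and 941 cells (3.90%) lay near a boundary between classes. All shares describe suspensions made by enzymatic dissociation, red cell lysis and a low-speed spin that removed most hepatocytes.

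Thioacetamide against saline asks which nonparenchymal cells and programmes differ in the fibrotic liver. Endothelial cells made up 43.9% (42.6 to 45.2) of the control library and 3.88% (3.42 to 4.38) of the TAA library, 11.3 times lower (9.93 to 12.9). Kupffer cells, the resident macrophages of the sinusoid, were 6.53% (5.90 to 7.20) and 1.97% (1.65 to 2.34), 3.31 times lower (2.70 to 4.08). Monocytes or macrophages were 5.03 times higher (4.33 to 5.88), at 17.7% (16.8 to 18.6) against 3.51% (3.05 to 4.02). Neutrophils were 3.80 times higher (3.33 to 4.37), at 17.7% (16.8 to 18.7) against 4.66% (4.12 to 5.24). Conventional dendritic cells 2, a class that includes migratory dendritic cells, were 4.69 times higher (3.60 to 6.20), cholangiocytes 3.104 times higher (2.43 to 3.998) and T cells 1.87 times higher (1.67 to 2.10). B cells, at 20.98% against 15.7%, were 1.34 times higher (1.23 to 1.46), and NK cells or innate lymphoid cells (NK or ILC), at 2.79% against 1.98%, 1.41 times higher (1.11 to 1.81).

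Because endothelial cells filled so much of the control library, the denominator mattered for lymphocytes. Among leukocytes alone, B cells were 35.9% in control and 24.1% in TAA, and NK or ILC 4.52% and 3.21%, so that both were lower in TAA, at ratios of 0.672 and 0.710. T cells were 18.0% (16.5 to 19.5) and 16.9% (15.9 to 17.9), a ratio of 0.938 whose shares had overlapping intervals. On that denominator monocytes or macrophages stayed 2.53 times and neutrophils 1.91 times higher, and the Kupffer ratio was 0.152. The mitochondrial filter removed 10.5% of control barcodes and 2.88%, 0.393% and 0.755% of the others, among barcodes with at least 200 genes. Without it the monocyte or macrophage ratio was 2.61. Cells were clustered and named anew for this, so that the ratio also depends on which clusters took the name. With classes from marker scores the Kupffer ratio was 0.814.

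**Figure D1:**
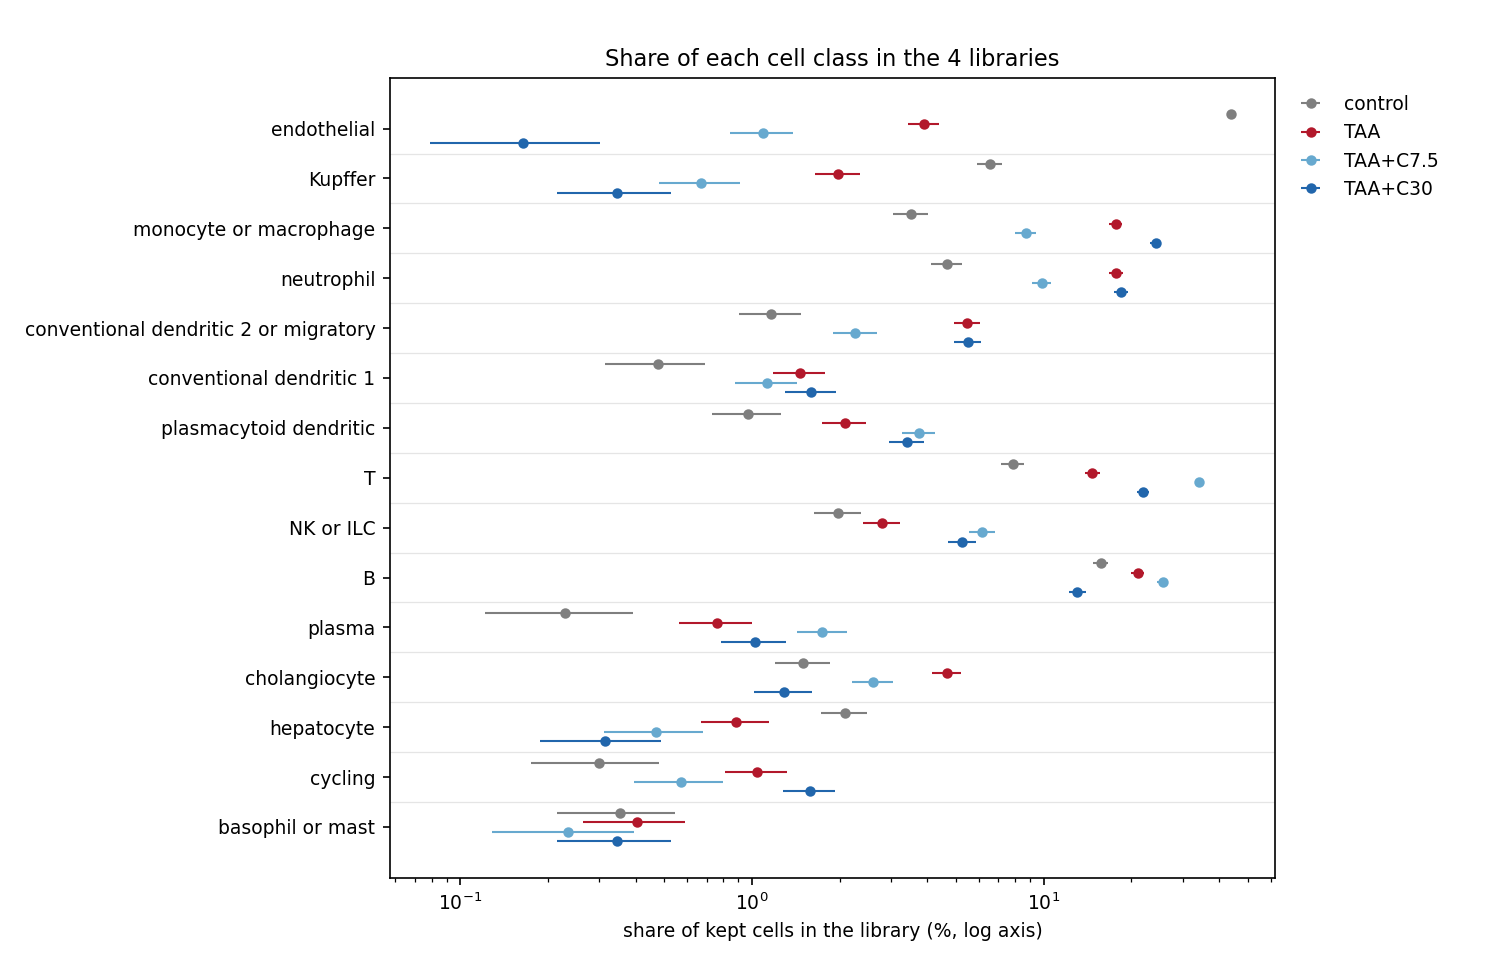
Share of kept cells (%, log axis) of each of the 15 named classes in the 4 libraries; points are shares and bars are exact 95% Clopper-Pearson intervals that cover counting error only. The endothelial share was 43.9% in control, 3.88% in TAA, 1.09% in TAA+C7.5 and 0.165% in TAA+C30.

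Within the endothelial class, Ednrb, Selp and Cd34 were higher in TAA and Rspo3 was lower. Ednrb reached 1949 CPM (UMIs scaled to a fixed class total) against 53.7, 36.3 times higher, at a log2 ratio of 4.94. Selp, which encodes P-selectin, was 18.2 times higher (392 against 21.5 CPM), and Cd34 was 17.4 times higher (14.4 to 21.1). Rspo3, a Wnt enhancer of central vein endothelium, was 111 times lower (37.9 to 540), on 3 UMIs in TAA. The groups drew on different clusters: control cells came mostly from a sinusoidal cluster with 1553 control and 2 TAA cells, while 115 TAA cells lay in a cluster led by Ednrb, Esm1, Selp and Cxcl10 that held 2 control cells. Those genes therefore partly define the clusters.

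Programmes in the endothelial class moved with this mix. The inflammatory cytokine and NF-kB list had a median log2 ratio of 1.04 (percentile 100 among random matched lists), with 13 of 21 measured members at least 1.5-fold higher, among them Tnfaip3 at 2.57 and Socs3 at 2.09, and 0 lower. In the interferon list 13 of 22 members were higher, with Isg15 at 2.57 (8.39 times), for a median of 0.94. Adhesion and vascular tone had a median of 0.49 with 8 of 17 higher, including Cxcl10 at 2.51. Capillarization, the gain of a continuous vessel programme, had a median of 0.36 with 7 of 18 members higher and 2 lower. Sinusoidal identity had a median of -0.28 (percentile 2.46), with Mrc1 at -0.82 and Lyve1 at 0.73, and 10 of 15 members lay within 1.5-fold. Periportal genes had a median of 0.49 with 6 of 14 higher, although Ltbp4 stood at -1.75, and pericentral genes -0.68 with 10 of 16 lower, including Cdh13 at -1.75. MHC class II genes had a median of 0.42, with 6 of 15 higher and H2-Aa at 1.02. Fibrillar matrix genes had a median of 0.54, with Col5a2 at 1.82, Fbn1 at 1.68 and Bgn at -1.18 among 11 measured. The cell cycle median was 0.44 (6 of 17 higher), the oxidative stress median 0.30 with Mt2 at 1.56, and the TGF-beta target median 0.06 with 16 of 17 members within 1.5-fold. The dissociation list, at 0.54 with Atf3 at 2.26 and Egr1 at 1.81, was higher as well, while the hepatocyte and erythroid lists, at -0.55 and -2.95, were lower.

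When each cluster shared by both libraries was given the same weight in both (matched weights, by the cells of the 2 libraries together), a comparison chosen after seeing the data, the inflammatory median was -0.25, adhesion -0.53, capillarization -0.03, sinusoidal identity 0.27, periportal -0.96, pericentral 1.10, fibrillar matrix -0.37 and dissociation -1.23, each opposite in direction. The interferon and MHC class II lists stayed higher on this footing, at 0.40 and 2.72. These values rest on 2 clusters with 37 and 23 of the 2487 control and 35 and 30 of the 250 TAA cells, which include neither the main sinusoidal nor the Ednrb-led cluster.

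Kupffer cells of the TAA library carried less Cd163 and Timd4 and more Mmp12 and Gpnmb. Cd163, a haemoglobin scavenger receptor, was at 49.8 against 530 CPM, 10.7 times lower (8.20 to 14.0), and Timd4 was at 109 against 381 CPM, a log2 ratio of -1.72. Mmp12 stood at 467 against 18.7 CPM, 24.96 times higher, and Gpnmb was 44.8 times higher (12.2 to 373), on 2 control UMIs. The Kupffer identity list had a median of -0.46 (percentile 0.200), with 7 of 16 members at least 1.5-fold lower and 2 higher, Id3 at 0.81 and Marco at 0.63, and a median of -1.55 by marker scores. The lipid-associated or scar-associated macrophage list, named after macrophages of fibrotic niches, had a median of 0.95 with 12 of 18 members higher, and of 1.90 by marker scores. Inflammatory genes had a median of 1.07 with 14 of 21 higher, Cxcl2 at 2.54 and Tnf at 1.98. The interferon median was 0.65 (12 of 22 higher, Isg15 at 2.19), and the matrix protease median 0.77 (10 of 16 higher, Timp3 19.8 times lower). Carry-over from other cells was not excluded for Timp3. Free RNA differed between these libraries, with endothelial markers in T cells at 371 CPM in control and 31.2 CPM in TAA. The cell cycle median was 0.54 with Mki67 at 1.56 and 9 of 20 higher, TGF-beta targets 0.16, MHC class II 0.17 with 12 of 16 members within 1.5-fold, and oxidative stress 0.23 with Hmox1 at -1.51. Classes from marker scores put that last median at -0.00038. The Kupffer medians of UMIs per cell were 1396 in control and 9301 in TAA, and in the same cells the dissociation list was at 0.46, the hepatocyte list at -1.19, although its summed CPM was 2333 in control and 2762 in TAA, and the erythroid list at -6.56.

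Gpnmb and Mmp12 were also the most raised genes of the monocyte or macrophage class in TAA. Gpnmb, at chromosome 6 from 49036546 to 49070929 of GRCm38, was at 443 against 2.43 CPM on 3 control UMIs, 182 times higher (62.4 to 885). Mmp12, a macrophage elastase gene at chromosome 9 from 7344381 to 7369499, was 219 times higher (39.3 to 8651), on 1 control UMI. Both lead a cluster of 25 control and 651 TAA cells that also carries Trem2 and the C1q genes. Gpnmb and Trem2 are among the markers that named the class, so that Gpnmb partly defines it. With matched weights the log2 ratios of Gpnmb and Mmp12, 5.19 and 4.12, were still 4.97 and 3.42. Ccl17 was 145 times lower (64.0 to 407) and Ddit4 12.5 times lower (9.74 to 16.0), although Ccl17 stood at a log2 ratio of 0.08 when classes came from marker scores.

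Lists in this class were mostly higher. The lipid-associated list had a median of 1.38 with 13 of 18 members higher and 1 lower. In the interferon list, with a median of 1.04, 16 of 22 members were higher, Ifit3 at 2.19 (135 against 21.9 CPM) and Irf7 at 1.83 (483 against 129 CPM), and 0 were lower. MHC class II had a median of 0.67 with 9 of 16 higher, Lgmn at 1.82 and H2-Eb1 at 1.32. Matrix proteases had a median of 0.64 (9 of 17 higher, 3 lower), cell cycle 0.62 (10 of 20 higher, Stmn1 at 1.89), oxidative stress 0.54 (8 of 16 higher, Fth1 at 1.59) and inflammatory genes 0.31 (6 of 21 higher and 2 lower, Il1a at 2.15, Cxcl1 at 1.90). With matched weights the MHC class II median was -0.34, the interferon median 0.65 and the protease median 0.13. The dissociation list was lower, at -0.37, with Hspa1b at -1.58 and Nr4a1 at -1.29, as was the hepatocyte list at -0.53.

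Lymphocytes of the TAA library had more Gzma and Pdcd1 in T cells and fewer killer cell transcripts in NK or ILC. In T cells Gzma was 3.97 times higher (3.41 to 4.63), though its log2 ratio of 1.88 was 0.54 with matched weights, and Nrarp was 5.69 times higher (3.65 to 9.34). Of the 4 T cell clusters, the largest in control held 189 control and 293 TAA cells, and the largest in TAA held 75 and 325. Exhaustion and regulation genes had a median of 0.32 with 4 of 17 higher and 0 lower, Pdcd1 at 1.29. The naive list had a median of -0.42 with 5 of 13 lower, Ccr9 at -1.17 and Satb1 at -1.07. Interferon genes had a median of 0.08, cytotoxic genes -0.12 with 4 of 18 higher, Gzmk at 1.26, and cell cycle genes 0.20 with 0 members past 1.5-fold. NK or ILC had a cytotoxic median of -0.72 with 10 of 17 lower and 1 higher (-0.45 by marker scores), Zeb2 at -2.61 and Ccl3 at -1.65. Klra8, of a receptor family with near-identical members, was 7.34 times lower (5.87 to 9.23) there, and Pmepa1 was 13.9 times (6.26 to 38.3) and Hilpda 9.95 times (5.46 to 20.2) higher. In control 35 of these cells lay in a cluster led by Xcl1 and Gzmc and 77 in the other, against 87 and 93 in TAA.

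B cells of the TAA library had lower activation genes. That list had a median of -0.47 with 8 of 17 lower and 2 higher, Myc at -1.48, Egr1 at -1.18 and Plac8 at 0.69. The dissociation and immediate early list was lower too, at -0.63 with 11 of 20 lower, while MHC class II was at 0.25 and interferon at 0.03. Tubb4b was 2.71 times (2.25 to 3.27) and Rbm3 2.44 times (2.28 to 2.62) higher. In control 753 B cells lay in a cluster led by Cr2 and Fcer2a and 136 in the other, against 103 and 1249 in TAA. Hspa1b, nearly identical in sequence to Hspa1a, was 6.60 times lower (5.85 to 7.45) in B cells, but its log2 ratio of -2.56 became 0.40 with matched weights, and in T cells it was 4.11 times lower (3.78 to 4.47). In neutrophils Rgs1 was 8.27 times (5.72 to 12.4) and Isg15 7.30 times (5.83 to 9.26) higher, and Tsc22d3 was 3.71 times lower (3.14 to 4.39). Of the neutrophils, 206 control and 456 TAA cells lay in the largest cluster of control, and 57 and 631 in the largest cluster of TAA.

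Slc15a2, at chromosome 16 from 36750177 to 36784962, stood apart in several classes of the TAA library. It had 0 UMIs in T cells against 150 in control, 119-fold lower with 3 counts taken for the 0. In neutrophils it had 0 against 38, 51.9-fold lower in the same way. These folds leave out the counting error of the control UMIs. Endothelial cells had 0 against 259. In B cells it had 1 against 286, 488 times lower (86.9 to 19349).

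RNA outside its cell of origin also differed between these libraries. Hepatocyte transcripts in B cells were at 658, 149, 66.1 and 38.6 CPM, and endothelial markers in T cells at 371, 31.2, 21.7 and 8.25 CPM. In TAA against control, the hepatocyte list was at -0.69 in T cells, -0.86 in B cells and -1.63 in NK or ILC, the dissociation list at -0.56, -0.63 and -0.25, and the erythroid list at -0.48 in T and -4.56 in B cells. Scaling by trimmed means in place of totals would raise log2 ratios of genes far above the added 10 CPM. It would add 0.16 in B cells, 0.19 in T cells and 0.23 in NK or ILC. The addition would be 0.21 in monocytes or macrophages, 0.20 in neutrophils and 0.12 in Kupffer cells. Genes nearer to 10 CPM would shift by other amounts.

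Ptgs2, which encodes the target of celecoxib, was at 1952, 1246, 1463 and 757 CPM in neutrophils of the 4 libraries. Of these neutrophils 0.379%, 4.82%, 8.86% and 38.4% lay in a cluster led by Ngp, Ltf and Camp, and no value with matched weights was computed for Ptgs2 there. Trimmed-mean scaling would add 0.44 to the neutrophil log2 ratio of Ptgs2 for TAA+C30 against TAA. The gene, at chromosome 1 from 150100031 to 150108227, was at 188 (164 to 214), 229 (221 to 238), 113 (99.9 to 127) and 172 (164 to 181) CPM in monocytes or macrophages, and at 601, 209, 231 and 158 CPM in conventional dendritic cells 2. T cells had 59.4, 8.27, 3.55 and 16.7 CPM, under 10% of the neutrophil level in each library, so that carry-over was not excluded. Monocytes or macrophages of control and TAA+C7.5 also lay under that 10%. Ptgs1, which encodes the constitutive enzyme, was at 53.5 (41.3 to 68.0), 148 (141 to 154), 90.2 (78.7 to 103) and 67.7 (62.4 to 73.2) CPM in monocytes or macrophages. It was also at 417, 273 and 380 CPM in endothelial cells of the control, TAA and TAA+C7.5 libraries and at 659 and 656 CPM in Kupffer cells of the control and TAA libraries. As a list, prostanoid and leukotriene genes in TAA against control had medians of 0.15 in endothelial cells (Slco2a1 at 1.22, Ptgs1 at -0.60, 15 of 17 within 1.5-fold), 0.00077 in Kupffer cells (Ptgis at -2.21, Slco2a1 at -1.92), 0.07 in monocytes or macrophages (Hpgds at 1.59, Ptgs1 at 1.31, Hpgd at -0.93), -0.18 in T cells and -0.13 in B cells. For Ptgis and Slco2a1 in Kupffer cells, carry-over from other cells was not excluded. In monocytes or macrophages 4 of 18 members were higher and 4 lower, and the median was -0.13 with matched weights and 0.37 with cells thinned to 1000 UMIs.

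The lower celecoxib dose against thioacetamide alone asks what celecoxib adds to the fibrotic liver. T cells were 34.1% (32.9 to 35.3) of the TAA+C7.5 library and 14.7% (13.8 to 15.6) of the TAA library, 2.32 times higher (2.15 to 2.51). NK or ILC were 2.21 times higher (1.84 to 2.65) and B cells 1.22 times higher (1.13 to 1.31). Monocytes or macrophages, at 8.68% (7.98 to 9.42), were 2.04 times lower (1.83 to 2.26), and neutrophils, at 9.85% (9.11 to 10.6), were 1.80 times lower (1.63 to 1.99). Conventional dendritic cells 2 were 2.41 times, cholangiocytes 1.79 times, Kupffer cells 2.94 times (2.04 to 4.30) and endothelial cells 3.56 times (2.70 to 4.75) lower, while plasma cells were 2.30 times and plasmacytoid dendritic cells 1.79 times higher. Without the mitochondrial filter, with cells clustered and named anew, the monocyte or macrophage ratio of 0.491 was 0.852. The filter had removed 2.88% of TAA and 0.393% of TAA+C7.5 barcodes with at least 200 genes. These are too few for such a change, so that class naming differed as well.

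Monocytes or macrophages of the TAA+C7.5 library had less Cxcl9 and Ly6a and more Rgcc and Fkbp5. Cxcl9, an interferon-gamma target at chromosome 5 from 92321347 to 92328079, was 15.9 times lower (8.31 to 34.8), and Ly6a was 3.44 times lower (3.14 to 3.77). Rgcc was 5.12 times (4.15 to 6.32) and Fkbp5, a glucocorticoid receptor target, 4.39 times (3.58 to 5.37) higher. The interferon list had a median of -0.55 with 10 of 22 members lower and 0 higher, Cxcl10 at -1.22, and the lipid-associated list a median of -0.54 with 9 of 18 lower and 0 higher, Spp1 at -1.92 (66.0 against 277 CPM) and Mmp12 at -1.15. MHC class II had a median of -0.48 with 5 of 16 lower, Ciita at -0.91 and H2-Aa at -0.80. Matrix proteases had a median of -0.26 (7 of 18 lower and 2 higher, Mmp14 at -1.21, Plaur at 0.96), oxidative stress -0.40 (3 of 16 lower, Mt1 at -0.81), cell cycle -0.28 (3 of 20 lower, Top2a at -0.75) and inflammatory genes -0.17 (3 of 21 lower and 1 higher, Il1a at -1.19, Il1rn at -1.09). The prostanoid median was -0.06, with 3 of 18 members lower and 3 higher, Ptgs2 at -0.96, Ptgs1 at -0.65, Ptgir at 0.99 and Hpgd at 0.74. The Gpnmb-led cluster held 651 of the TAA and 144 of the TAA+C7.5 cells, and that led by F13a1, Fn1 and Chil3 held 322 and 238. With matched weights the lipid-associated median was -0.04, MHC class II -0.10, proteases -0.08 and oxidative stress -0.23. The dissociation list was at 0.25 and the hepatocyte list at -0.09.

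T cells of the TAA+C7.5 library carried more Pdcd1, Tox and Ccl3. Pdcd1, which encodes the inhibitory receptor PD-1, was at a log2 ratio of 1.77, Tox at 1.44 and Ccl3 at 1.79. Exhaustion and regulation genes went both ways, with 4 of 17 higher and 3 lower (Tnfrsf4 at -0.96, Icos at -0.89) and a median of -0.02. The cytotoxic median was 0.21 with 5 of 18 higher and 1 lower. Interferon genes had a median of -0.30 with 2 of 21 lower, Ifi27l2a at -0.77, and 0 higher. The naive list was at 0.15, with Ccr7 at 0.42 and S1pr1 at -0.61, cell cycle at -0.0048 and prostanoid genes at -0.05. By the fixed rule AC102496.1 (6.17 times, 4.93 to 7.80) and Pisd-ps2, a pseudogene (6.92 times, 5.03 to 9.72), were highest and Ly6a (2.68 times, 2.40 to 3.01) and Cd40lg (3.39 times, 2.61 to 4.44) lowest. The cluster led by Pdcd1, Tox and Gzmk held 80 of the TAA and 687 of the TAA+C7.5 T cells, and another held 247 and 670. With matched weights the log2 ratio of Cd40lg went from -1.30 to -0.66.

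NK or ILC had a cytotoxic median of 0.68, with 9 of 17 higher and 0 lower, but of 0.30 with cells thinned to 1000 UMIs and 0.40 by marker scores. Ccl3 was 5.74 times higher (4.95 to 6.67), Ccl4 stood at 1.58, and Gzmc, which leads a cluster, was 4.38 times (3.32 to 5.88) and Rbpj 3.12 times (2.11 to 4.75) lower. In B cells AC102496.1 was 8.31 times higher (7.25 to 9.57), and Crip1 was 2.97 times (2.75 to 3.20) and Ccnd2 3.16 times (2.49 to 4.07) lower. Their activation list had a median of -0.12 (Jchain at 1.22, Egr1 at -0.75), interferon -0.25, MHC class II 0.06 and prostanoid genes -0.05. Slc15a2 was 419 times higher (74.4 to 16639) in B cells, on 1 TAA UMI. In NK or ILC it had 37 UMIs against 0, 16.4-fold higher with 3 counts taken for the 0. Neutrophils had Fbxo31 3.35 times (2.46 to 4.56) and Fkbp5 3.96 times (2.58 to 6.10) higher, and Ifi27l2a 2.98 times (2.71 to 3.29) and Rsad2 2.98 times (2.55 to 3.51) lower, with 631 of the TAA and 155 of the TAA+C7.5 cells in the largest TAA cluster. The dissociation list was higher, at 0.46 in T cells, 0.48 in B cells and 0.62 in NK or ILC, and the hepatocyte list was at -0.26, -0.29 and -0.07. Trimmed-mean scaling would add -0.12 in B cells and -0.11 in monocytes or macrophages.

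The 65 endothelial cells of the TAA+C7.5 library had more Rspo3 and less Selp than those of the TAA library. Rspo3 was 112 times higher (34.7 to 571), on 30 against 3 UMIs, Ccn2 was 10.2 times higher (6.59 to 15.8), and Selp stood at -2.14. Pericentral genes had a median of 0.46 with 7 of 16 higher, Lfng at 1.72, and periportal genes -0.37 with 5 of 14 lower. Capillarization was at -0.30 (3 of 16 lower, Vwf at -2.27 on 2 UMIs, Esm1 at -1.62), adhesion at -0.21 (7 of 17 lower, 3 higher), sinusoidal identity at -0.07 with Lyve1 at 1.13, and inflammatory genes at -0.24 (4 of 19 lower, Tnfaip3 at -2.27). The interferon median was -0.64 with 12 of 22 lower, and MHC class II was at -0.54 but at 0.52 by marker scores. Prostanoid genes were at -0.31 with Ltc4s at 1.47, fibrillar matrix at -0.07, TGF-beta targets at 0.07, cell cycle at -0.26, oxidative stress at 0.39 with Ftl1 at 1.06, dissociation at -0.16 and hepatocyte genes at -0.13. Of these cells 7 lay in the Ednrb-led cluster that held 115 of the TAA cells, and 15 in the main sinusoidal cluster of control.

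The higher dose against thioacetamide alone asks the same of celecoxib at 30 mg/kg. Monocytes or macrophages were 24.2% (23.1 to 25.3) of the TAA+C30 library, 1.37 times higher than in TAA (1.27 to 1.48), and neutrophils, at 18.4% (17.4 to 19.4), were 1.04 times higher (0.955 to 1.13). T cells, at 21.9% (20.9 to 23.0), were 1.49 times (1.37 to 1.62) and NK or ILC 1.88 times (1.56 to 2.27) higher, and B cells were 1.61 times lower (1.47 to 1.76). Endothelial cells numbered 10, a share of 0.165% (0.0791 to 0.303) that was 23.5 times lower (12.6 to 49.7). Kupffer cells were 5.69 times (3.57 to 9.51) and cholangiocytes 3.62 times lower, cycling cells 1.52 times and plasmacytoid dendritic cells 1.63 times higher, and conventional dendritic cells 2 stood at a ratio of 1.01. Of the cycling cells, 2 clusters that carry Prtn3 held 5 and 4 TAA and 32 and 25 TAA+C30 cells, while the others went from 26 to 30 and from 32 to 9. Without the mitochondrial filter, with cells clustered and named anew, the monocyte or macrophage ratio was 2.46. The barcodes removed by the filter are too few for such a change, so that class naming differed as well. With classes from marker scores the Kupffer and endothelial ratios of 0.176 and 0.0425 were 0.443 and 0.127. At clustering resolution 0.5 cycling cells were at 0.955, and among leukocytes neutrophils were at 0.935.

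Monocytes or macrophages of the TAA+C30 library had more F13a1 and Hopx and less Vcam1 and Ly6a. F13a1, at chromosome 13 from 36867178 to 37050244, was 3.59 times higher (3.37 to 3.83) but leads the largest cluster of the class in this library, with 918 of its cells against 322 in TAA, and its log2 ratio of 1.75 was 0.51 with matched weights. Hopx was 3.49 times higher (3.18 to 3.84) and 0.60 in log2 with matched weights. Vcam1 was 4.39 times (3.94 to 4.90) and Ly6a 3.43 times (3.26 to 3.61) lower, log2 ratios of -1.90 and -1.73 that were -0.75 and -1.03 with matched weights. The lipid-associated list had a median of -0.70 with 12 of 18 lower and 0 higher, Fabp4 at -1.37, Cd36 at -1.29 and Lgals3 at 0.49, but 0.14 with matched weights. The interferon median was -0.48 with 10 of 22 lower and 0 higher, Cxcl9 at -1.04 and Irf7 at -0.94. MHC class II was at -0.69 (9 of 16 lower, H2-Aa at -1.12, H2-Eb1 at -1.02) and -0.23 with matched weights. Proteases were at -0.18 (Mmp13 at -1.55, Mmp14 at -1.05, Mmp8 at 1.75), oxidative stress at -0.22 with 1 of 16 lower, and inflammatory genes at -0.16 (Il1a at -1.50, Ccl2 at 0.82). With matched weights these were at 0.04, 0.03 and -0.04. The cell cycle median was 0.09 (3 of 20 higher, Ccnb2 at 0.97, Hmgb2 at 0.82) and -0.30 with doublets kept and cells clustered and named anew. In the main setting the class included a cluster led by Prtn3, F13a1 and Ccnb2, with 4 TAA and 61 TAA+C30 cells. Prostanoid genes were at -0.08 (Ptgs1 at -1.02, Hpgds at -0.97, Alox5ap at 0.89), the dissociation list at 0.22 and the hepatocyte list at -0.17.

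**Figure D2:**
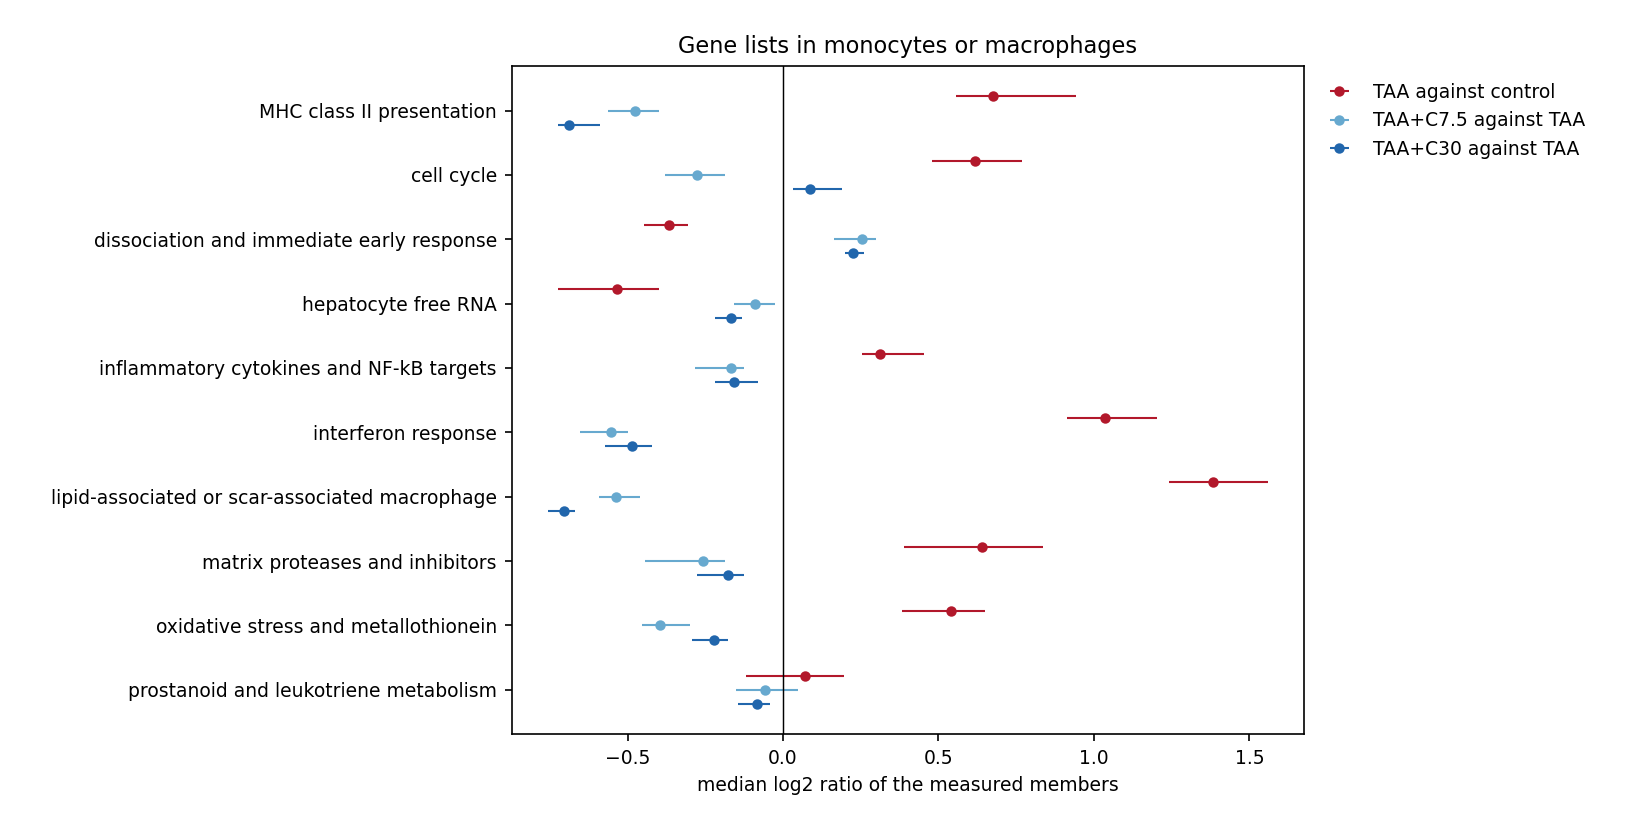
Median log2 ratio of the measured members of 10 gene lists in monocytes or macrophages, for TAA against control, TAA+C7.5 against TAA and TAA+C30 against TAA; points are medians and bars are 95% ranges over redrawn counts, which cover counting error only. The lipid-associated list was at 1.38, -0.54 and -0.70, and with matched weights for clusters the last was 0.14.

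Neutrophils of the TAA+C30 library had more Ltf and Camp, which encode granule proteins. Ltf was 6.99 times higher (6.66 to 7.34) and Camp 6.89 times higher (6.70 to 7.09). These genes lead a cluster with 429 cells in TAA+C30 and 55 in TAA, and with matched weights their log2 ratios of 2.79 and 2.78 were 0.49 and 0.44. AC122252.2 was 4.81 times (3.96 to 5.89) and Clec4n 3.98 times (3.37 to 4.71) lower, log2 ratios of -2.02 and -1.82 that were -1.01 and -0.20 with matched weights. Trimmed-mean scaling would add 0.44 to log2 ratios of genes far above the added 10 CPM in this class.

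T cells of the TAA+C30 library again had more Ccl3, Pdcd1 and Tox, at log2 ratios of 1.43, 1.26 and 1.03, and Gzma at 1.13. The cytotoxic list had a median of 0.39 with 4 of 18 higher and 0 lower, exhaustion 0.16 with 3 of 17 higher and 0 lower, naive genes -0.17 and interferon genes -0.24 with Rsad2 at -0.72 and Ifit1 at -0.69. Cell cycle was at 0.01 and prostanoid genes at -0.02. Hspa1a was 5.87 times (5.41 to 6.39) and Hspa1b 4.84 times (4.50 to 5.22) higher, and Hist1h1e 2.31 times (1.84 to 2.91) and Abcb1b 2.14 times (1.80 to 2.54) lower. In NK or ILC the cytotoxic median was 0.40 with 4 of 18 higher, Ccl3 at 1.80 and Ifng at 1.12. Hspa1b was 4.66 times (4.01 to 5.44) and Hspa1a 4.42 times (3.75 to 5.22) higher there, Stmn1 3.17 times (2.27 to 4.49) and Lig1 3.13 times (1.82 to 5.65) lower, log2 ratios of -1.49 and -1.26 that were -0.094 and -0.54 by marker scores. In B cells Hspa1a was 6.66 times (5.85 to 7.58) and Slc15a2 332 times higher, on 102 UMIs against 1, and Ccnd2 was 3.38 times (2.49 to 4.69) and Asph 2.34 times (1.72 to 3.24) lower. Activation was at 0.11 (Myc at 0.74, Cd83 at 0.72, Cd9 at -0.81), interferon at -0.21, MHC class II at 0.02 and prostanoid genes at -0.13. The heat shock genes belong to the dissociation list, which was at 0.54, 0.74 and 0.71 in T cells, NK or ILC and B cells, with 15 of 20 members higher in B cells. The hepatocyte list was at -0.26, -0.80 and -0.40.

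The higher against the lower dose asks whether the effect of celecoxib depends on dose. In TAA+C30 monocytes or macrophages were 2.79 times (2.52 to 3.09), neutrophils 1.87 times (1.69 to 2.07), conventional dendritic cells 2 2.43 times and cycling cells 2.77 times higher. T cells were 1.56 times, B cells 1.96 times, NK or ILC 1.17 times and cholangiocytes 2.02 times lower. Endothelial cells were 6.62 times lower (3.38 to 14.4) and Kupffer cells 1.94 times lower, but by marker scores the Kupffer ratio was 1.35 and the endothelial ratio of 0.151 was 0.365. In monocytes or macrophages the cell cycle median was 0.37 (7 of 20 higher, Ccnb2 at 1.25, Ube2c at 1.04), and a cluster led by Prtn3, F13a1 and Ccnb2 held 61 TAA+C30 and 3 TAA+C7.5 cells. Interferon was at 0.15 with Cxcl9 at 1.28, proteases at 0.17, oxidative stress at 0.11 with Mt1 at 0.93, MHC class II at -0.25, inflammatory genes at -0.01 with Ccl2 at 0.84, and prostanoid genes at -0.09 with Ptgs2 at 0.57. The lipid-associated median of -0.09 (Spp1 at 1.31, Fabp4 at -1.79) turned to 0.19 with matched weights.

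In T cells the same comparison gave medians of -0.26 for naive (Ccr7 at -0.63), 0.16 for cytotoxic (Gzma at 0.97), 0.14 for exhaustion (Maf at 0.87), 0.08 for interferon, 0.03 for cell cycle and 0.01 for prostanoid genes. In NK or ILC the cytotoxic median was -0.20 (Prf1 at -0.80, Cxcr6 at 1.00), and -0.00052 with matched weights. In B cells activation was at 0.03 with Egr1 at 1.38, interferon at 0.10, MHC class II at 0.04 and prostanoid genes at -0.15. The dissociation list was at 0.14 in T cells, 0.24 in NK or ILC, 0.39 in B cells and 0.07 in monocytes or macrophages, and the hepatocyte list at -0.03 in T cells, -0.35 in B cells and -0.09 in monocytes or macrophages. Trimmed-mean scaling would add 0.15 in B cells, 0.13 in NK or ILC, 0.14 in monocytes or macrophages and 0.49 in neutrophils.

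A last comparison asks whether genes that differed between TAA and control lay closer to control in the celecoxib libraries. In monocytes or macrophages, of a median of 685 genes that differed at least 2-fold, 88.5% (87.0 to 90.3 over 20 random splits of the TAA cells) were on the control side in TAA+C7.5 and 75.5% (73.9 to 78.9) in TAA+C30. The median fraction of the log2 difference returned was 0.332 and 0.234, and counts simulated with no difference gave 49.0% and 49.5%. The Gpnmb-led cluster held 12.6%, 57.2%, 27.9% and 23.6% of this class, and with matched weights for clusters of the 3 libraries the percentages were 62.5% (57.9 to 66.1) and 51.6% (46.9 to 55.3). With these weights the median fractions returned were 0.0819 and 0.0122. NK or ILC had 61.5% and 57.4% of 804.5 genes on the control side, with 49.7% and 49.9% simulated. Neutrophils had 58.2% and 43.4% of 393.5 genes, and with genes that differed at least 3-fold the former was 43.5%, while trimmed-mean scaling put the latter at 50.6%. T cells had 52.4% and 43.6% of 223.5 genes, and B cells 49.5% and 45.7% of 197 genes, against 51.4%, 50.0%, 49.0% and 50.1% simulated. Genes that differed at least 3-fold put T cells at 32.8% and 32.9% and B cells at 40.0% and 28.6%, while B cells in TAA+C7.5 were at 59.0% with genes at least 1.5-fold different and at 60.5% with all genes kept. The directions were unequal: in TAA+C30, 70.6% of the neutrophil genes higher in TAA and 25.7% of those lower lay on the control side, 89.7% and 62.5% in monocytes or macrophages, 63.0% and 52.6% in NK or ILC, 52.2% and 38.8% in T cells and 62.7% and 40.5% in B cells. In TAA+C7.5 these were 72.0% and 50.4%, 92.7% and 84.8%, 67.4% and 56.7%, 61.4% and 46.9%, and 61.5% and 45.5%. For neutrophils of TAA+C30 against TAA, trimmed-mean scaling would add 0.44 to log2 ratios of genes far above the added 10 CPM. That would move genes of both directions upward, and the split by direction was not computed with it. The single TAA mouse enters both sides of the return comparison. Any peculiarity of that mouse or its library would also place other mice on the control side. Dissociation and immediate early genes were kept in the return, and their part in it was not tested. Their summed CPM in monocytes or macrophages was 20069, 14915, 16672 and 17160. It was lowest in TAA there and in T cells, B cells and NK or ILC, but not in neutrophils.

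**Figure D3:**
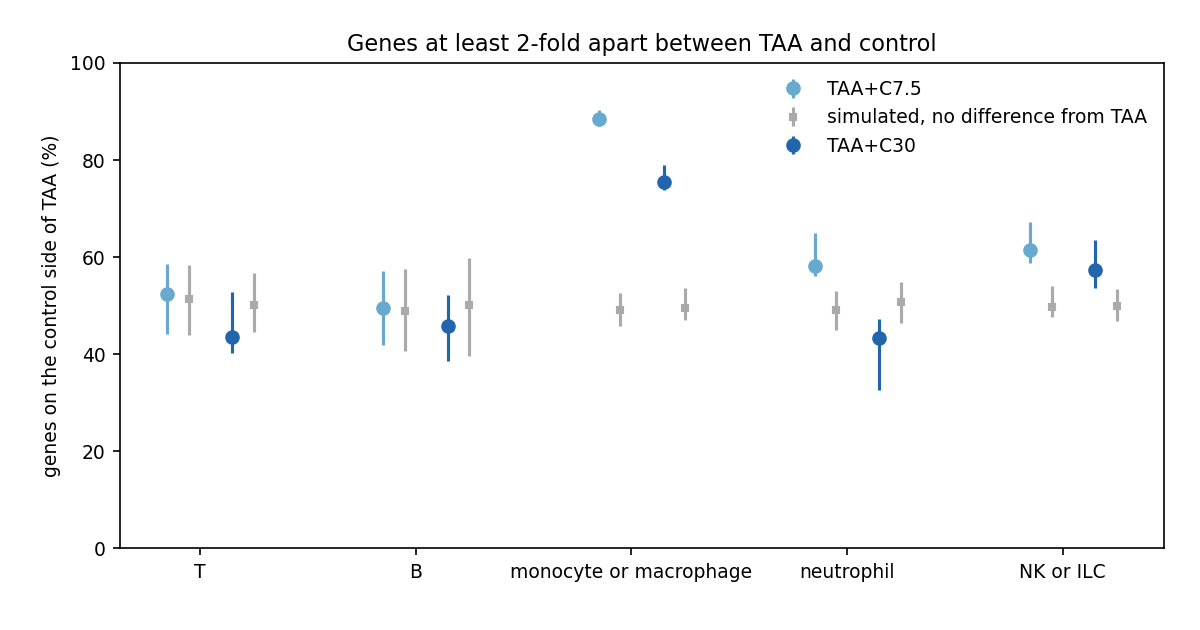
Percentage of genes at least 2-fold different between TAA and control that lay on the control side in TAA+C7.5 and TAA+C30, in the 5 classes with at least 100 cells in each library; points are medians and bars the lowest to highest of 20 random splits, and grey squares are counts simulated with no difference from TAA. Monocytes or macrophages stood at 88.5% and 75.5%, and at 62.5% and 51.6% with matched weights for clusters, which are not drawn.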

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

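The tests of cell filters, of incomplete dissociation, of depth and of gene loss were chosen only after the result was seen.

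Several values lay on opposite sides of TAA in the celecoxib libraries, and in each case the difference was not tested. The B cell share ratio to TAA was 1.22 in TAA+C7.5 and 0.623 in TAA+C30. Cycling cells stood at 0.549 and 1.52, and monocytes or macrophages at 0.491 and 1.37, but at clustering resolution 0.5 cycling cells of TAA+C30 were at 0.955, below TAA as well. Of the cycling cells, a cluster of 32 TAA cells held 3 in TAA+C7.5 and 9 in TAA+C30, and 2 clusters that carry Prtn3 held 5 and 4 in TAA, 2 and 3 in TAA+C7.5 and 32 and 25 in TAA+C30. The naive T list in T cells had medians of 0.15 and -0.17, and the cell cycle list in monocytes or macrophages of -0.28 and 0.088. The latter was -0.30 with doublets kept and cells clustered and named anew.

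Endothelial and Kupffer shares were lower in the TAA library than in control. The Kupffer part depends on class assignment, since the share ratio of 0.302 was 0.814 by marker scores. The mitochondrial filter is argued against as the cause, since without it the endothelial share of TAA was 1.02 times the filtered share. For lysis of endothelial cells that leaves their RNA free in the suspension, endothelial marker CPM in T cells of TAA was 0.0842 (0.0702 to 0.1004) of that in control. This met the bound set beforehand against lysis. Hepatocyte transcripts in T cells were lower too, at 120 CPM in TAA and 497 CPM in control. Less free RNA from any source could give the same result, so the test does not decide on lysis. Incomplete release from fibrotic tissue and a loss in the animal under thioacetamide cannot be told apart, because either would lower the Kupffer share of leukocytes, which was 0.152 of control. More monocytes or macrophages and neutrophils, whose shares were higher in TAA, would also lower these shares, which do not show absolute cell numbers. No test here separates these possibilities, and each may hold.

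Slc15a2 in the TAA library and mt-Nd3 in the TAA+C7.5 library were close to 0 UMIs in leukocytes. Low depth does not explain Slc15a2, since 1400 UMIs would be found over 5 classes at the control level and 1 was, nor does loss of the gene from the genome of the mouse, since cholangiocytes of the TAA library had 81.6% of its lowest level in control and TAA+C7.5. For mt-Nd3, a mitochondrial variant of the TAA+C7.5 mouse that sends its reads to the nuclear copy Gm28438 may be the cause, as the transcripts differ at 1 base of 345 aligned. A genetic difference of the TAA mouse against the other 3 stays open: 0 other genes were close to 0 in TAA, a result set beforehand to count against it, but that bound was wrong, since the TAA+C7.5 library likewise had 1 such gene and a single base can account for it. The design names no biological cause for either gene, and an effect of the treatments on them was not tested.

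Fkbp5 and Tsc22d3, which glucocorticoids induce, were higher in TAA+C7.5 than in TAA in the 5 classes. Their log2 ratios were 1.64 and 1.30 in monocytes or macrophages, 1.47 and 1.31 in neutrophils, 1.03 and 0.80 in B cells, 0.84 and 0.58 in T cells and 0.49 and 0.71 in NK or ILC. Tsc22d3 was also higher in TAA+C30 than in TAA in these classes (0.42 to 0.76) and lower in TAA than in control (-0.80 to -1.80), so that for this gene the TAA library was the lowest of the 4. Different glucocorticoid exposure, different time of day at sampling and dissociation stress each may contribute and cannot be told apart here. The glucocorticoid and stress tests fell between their bounds. The time of day test met the bound written beforehand against that cause. It did not meet it once counting ranges were required, a condition outside the written bound, so that time of day is left open. A glucocorticoid list without these genes was above 0 and at or above percentile 95 in 3 of 5 classes. Evening minus morning clock genes lay within 0.25 of 0 in 3 of 5 classes, but with a counting range inside 0.5 of 0 in 2 of them. The mean of Fkbp5, Tsc22d3 and Ddit4 was under -0.3 for TAA+C30 against TAA+C7.5 in 2 of 5 classes, monocytes or macrophages and neutrophils. The dissociation list was higher in TAA+C30 in T cells, B cells, NK or ILC and monocytes or macrophages. In neutrophils it was lower there, at 12674 against 19355 summed CPM. The dose of celecoxib, confounded with the mouse, stays open as well.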

How the results depend on the processing

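Shares of leukocytes alone, the haemoglobin-rich part counted as endothelial, matched weights of clusters (also in the return) and all genes kept in the return were tests chosen only after the results were seen. No paired analysis was possible because each group has 1 mouse and the groups share fewer than 2 replicate numbers. Of 472 alternative share ratios 430 lay within the counting interval, 37 outside it and 5 opposite in direction to an interval that left out no difference. Of 472 alternative shares 379 lay within and 93 outside. For 1619 alternative list medians these counts were 1258, 342 and 19, for 360 gene ratios 279, 79 and 2, and for 60 percentages of genes on the control side 42, 16 and 2. For gene ratios the interval here paired opposite exact Poisson limits of the libraries compared. For the percentages it was an exact binomial interval over genes taken as independent, which need not hold. Values outside an interval that spanned no difference also changed sides, for 3 share ratios, 15 list medians and 3 percentages. Intervals of shares, share ratios, medians and gene ratios cover counting error only, and none covers the spread between mice. A value outside them need not exceed that spread, which 1 mouse per group cannot show. Few cells limit the rare classes: 10 endothelial cells in TAA+C30 gave no gene comparison, and 65 in TAA+C7.5 left several genes with 1 to 3 UMIs. Matched weights gave list values for 137 of 153 medians, thinning to 1000 UMIs 142, the stricter count filter 141, marker scores 150 and the reduced total 131, since the others had too few shared clusters or members, or were lists of the genes left out. Leukocyte shares exist for leukocyte classes only, and the haemoglobin-rich part applies to endothelial cells only.

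The values of the main results that left their interval, and all that turned from an interval that left out no difference, follow by setting, and the cause was not tested in any of them. Lipid-associated, interferon, protease and prostanoid genes, and MHC class II, oxidative stress and cell cycle unless another class is named, are those of monocytes or macrophages. Share ratios among leukocytes for TAA against control were opposite for B cells (0.672), NK or ILC (0.710) and T cells (0.938), and were 0.152 for Kupffer cells, 2.53 for monocytes or macrophages and 1.91 for neutrophils. For TAA+C7.5 against TAA they were 1.12 for B cells and 2.14 for T cells, and for TAA+C30 against TAA 0.561 for B cells, 1.34 for T cells, 1.23 for monocytes or macrophages and 0.935 for neutrophils. Without the mitochondrial filter the ratios for TAA against control were 0.401 for Kupffer cells, 0.108 for endothelial cells and 2.61 for monocytes or macrophages. The last class stood at 0.852 for TAA+C7.5 and 2.46 for TAA+C30 against TAA. Cells were clustered and named anew for this setting, so that these values do not show the filter alone. The same holds for the settings with at most 10% mitochondrial UMIs, at least 1000 UMIs per cell and doublets kept. At most 10% mitochondrial UMIs gave, for TAA against control, 1.22 for B cells, 0.449 for Kupffer cells and 4.29 for monocytes or macrophages. It gave endothelial ratios of 0.0984 for TAA+C30 against TAA and 0.349 against TAA+C7.5. Cells with at least 1000 UMIs gave 1.23 for B cells and 0.375 for Kupffer cells for TAA against control, and for neutrophils 0.454 for TAA+C7.5 against TAA and 2.20 for TAA+C30 against TAA+C7.5. Resolution 0.5 gave 1.03 for NK or ILC for TAA against control and turned cycling cells to 0.955 for TAA+C30 against TAA. Classes by marker scores gave a Kupffer ratio of 0.814 for TAA against control, 0.443 for TAA+C30 against TAA and, in the opposite direction, 1.35 against TAA+C7.5. They gave endothelial ratios of 0.127 and 0.365 for those last comparisons, and 1.54 for monocytes or macrophages for TAA+C30 against TAA.

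Medians by marker scores for TAA against control were -1.55 for Kupffer identity, -0.45 for NK or ILC cytotoxic genes, 0.97 for lipid-associated genes, -0.33 for sinusoidal identity and -0.00038 for Kupffer oxidative stress, the last turned. For TAA+C7.5 against TAA they were 0.52 for endothelial MHC class II, turned, -0.45 for capillarization, 0.40 for NK or ILC cytotoxic genes, -0.44 for lipid-associated genes and -0.30 for sinusoidal identity, and for TAA+C30 against TAA -0.031 for prostanoid genes. The log2 ratio of Ccl17 in monocytes or macrophages turned to 0.079.

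With matched weights of clusters, medians for TAA against control turned to -0.34 for MHC class II and, in endothelial cells, to -0.033 for capillarization, -1.23 for dissociation, -0.53 for adhesion, -0.37 for fibrillar matrix, -0.25 for inflammatory genes, 1.10 for pericentral genes, -0.96 for periportal genes and 0.27 for sinusoidal identity. They were 0.65 for interferon genes, -0.23 for naive T genes and -0.13 for prostanoid genes, and Hspa1b in B cells turned to 0.40. For TAA+C30 against TAA they turned to 0.14 for lipid-associated genes, 0.045 for proteases and 0.034 for oxidative stress, and were 0.50 for NK or ILC cytotoxic genes and -0.0055 for prostanoid genes. For TAA+C7.5 against TAA they were -0.042 for lipid-associated genes and 0.10 for naive T genes. For TAA+C30 against TAA+C7.5 they were 0.019 for T cell exhaustion, -0.00052 for NK or ILC cytotoxic genes and 0.063 for interferon genes, and turned to 0.19 for lipid-associated genes. The endothelial values for TAA against control rest on a pair of clusters with 37 and 23 control and 35 and 30 TAA cells.

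TMM factors gave, for TAA against control, -0.36 for B cell activation, -0.34 for Kupffer identity, -0.51 for NK or ILC cytotoxic genes, 1.22 for interferon genes, 1.58 for lipid-associated genes and -0.24 for naive T genes. For TAA+C7.5 against TAA they gave -0.65 for interferon genes, -0.64 for lipid-associated genes, 0.12 for naive T genes and -0.16 for sinusoidal identity. For TAA+C30 against TAA+C7.5 they gave 0.16 for B cell activation, -0.087 for NK or ILC cytotoxic genes, 0.27 for interferon genes and, turned, 0.048 for lipid-associated genes. DESeq2 size factors gave, for TAA against control, -0.35 for Kupffer identity, -0.55 for NK or ILC cytotoxic genes, -0.28 for naive T genes and -0.24 for sinusoidal identity. They gave -0.61 for lipid-associated genes, 0.12 for naive T genes and -0.19 for sinusoidal identity for TAA+C7.5 against TAA, and -0.66 for lipid-associated genes for TAA+C30 against TAA. For TAA+C30 against TAA+C7.5 they gave -0.12 for NK or ILC cytotoxic genes, 0.26 for interferon genes and, turned, 0.033 for lipid-associated genes. With each cell scaled to the same total, medians for TAA against control were -0.32 for Kupffer identity and -0.20 for sinusoidal identity, and for TAA+C7.5 against TAA -0.66 for interferon genes and 0.11 for naive T genes. Lipid-associated genes were at -0.66 for TAA+C30 against TAA and, turned, at 0.0052 against TAA+C7.5, with interferon genes at 0.22.

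In cells thinned to 1000 UMIs, medians for TAA against control were -0.72 for B cell activation, 0.49 for capillarization, 1.27 for endothelial inflammatory genes, 0.37 for prostanoid genes and -0.19 for sinusoidal identity. For TAA+C7.5 against TAA they were 0.077 for T cell exhaustion, 0.30 for NK or ILC cytotoxic genes and 0.13 for sinusoidal identity, and for TAA+C30 against TAA 0.34 for B cell activation, 0.32 for T cell exhaustion and -0.65 for lipid-associated genes. For TAA+C30 against TAA+C7.5 they were 0.24 for interferon genes and -0.0071 for lipid-associated genes. At least 50 UMIs per gene gave -0.74 for B cell activation, 1.21 for endothelial inflammatory genes and 0.26 for prostanoid genes for TAA against control, and 0.29 for B cell activation and -0.18 for prostanoid genes for TAA+C30 against TAA. No count filter gave 0.29 for capillarization for TAA against control and -0.039 for prostanoid genes for TAA+C30 against TAA. A pseudocount of 1 CPM gave -0.70 for B cell activation, 0.55 for T cell exhaustion and 1.21 for endothelial inflammatory genes for TAA against control, and -0.20 for prostanoid genes for TAA+C30 against TAA. Totals without hepatocyte, haemoglobin, mitochondrial and ribosomal protein genes gave 0.45 for T cell exhaustion and -0.25 for sinusoidal identity for TAA against control, -0.19 for B cell activation and 0.13 for naive T genes for TAA+C7.5 against TAA, -0.67 for lipid-associated genes for TAA+C30 against TAA, and -0.13 for NK or ILC cytotoxic genes for TAA+C30 against TAA+C7.5. With doublets kept and cells clustered and named anew, medians for TAA against control were 0.91 for endothelial inflammatory genes and -0.13 for prostanoid genes. They were 0.73 for NK or ILC cytotoxic genes for TAA+C7.5 against TAA, and turned to -0.30 for cell cycle for TAA+C30 against TAA.

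On the control side, genes at least 1.5-fold different gave 59.0% for B cells, 57.9% for NK or ILC and 77.8% for monocytes or macrophages in TAA+C7.5, and 53.5% for NK or ILC and 65.4% for monocytes or macrophages in TAA+C30. Genes at least 3-fold different gave 40.0% for B cells, 32.8% for T cells and, turned, 43.5% for neutrophils in TAA+C7.5, and 28.6% for B cells, 32.9% for T cells and 36.9% for neutrophils in TAA+C30. TMM factors turned neutrophils in TAA+C30 to 50.6%. All TAA cells used for both steps gave 78.8% for NK or ILC and 90.9% for monocytes or macrophages in TAA+C7.5, and 78.9% for NK or ILC in TAA+C30. All genes kept gave 60.5% for B cells in TAA+C7.5. Matched weights of clusters gave 62.5% in TAA+C7.5 and 51.6% in TAA+C30 for monocytes or macrophages.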

Other observations

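The tests on Pdcd1, Tox and Gzmk were chosen only after the results were seen. The single genes close to 0 were noticed in the data, and the added lists were chosen after the values of Fkbp5 and Tsc22d3 and before their own.

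T cells with at least 1 Pdcd1 UMI, after thinning to 1000 UMIs per cell, made up 0.941% of the control, 4.23% of the TAA, 13.4% of the TAA+C7.5 and 10.7% of the TAA+C30 T cells. Tox was found in 4.71%, 6.07%, 18.6% and 15.4%, and Gzmk, a granzyme of memory and exhausted cells, in 1.88%, 6.83%, 10.7% and 7.92%. Without thinning the shares were 2.92%, 9.84%, 20.3% and 17.2% for Pdcd1, 23.4%, 24.3%, 30.4% and 29.4% for Tox, and 4.49%, 14.3%, 16.0% and 16.3% for Gzmk. The median T cell had 4651, 4897, 2188 and 2749.5 UMIs. In B cells, which should lack these genes and had medians of 3175, 3309, 1558 and 1905 UMIs, shares without thinning were at most 0.148% for Pdcd1, 0.379% for Tox and 0 for Gzmk. As CPM of the T cell sum, Pdcd1 was at 11.3, 42.2, 168 and 115, Tox at 85.9, 76.3, 224 and 166, and Gzmk at 15.7, 51.5, 103 and 81.2. Thinning left out 20, 22, 166 and 91 T cells of lower depth, and the genes lead a cluster with 13, 80, 687 and 306 cells.

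Some other cell populations differed between libraries in their cell numbers, and some differed little. A small cholangiocyte cluster led by Dmbt1, Chil4, Spink4 and Tff2, genes of mucus-secreting epithelium, held 0, 0, 18 and 14 cells, beside 85, 300, 137 and 64 in the main cholangiocyte cluster. Patrolling monocytes led by Ace numbered 94, 145, 121 and 91. Neutrophils led by Ccrl2, Slfn4 and Il1rn numbered 57, 631, 155 and 249. T cells led by Icos, Il17a and Rora numbered 189, 293, 269 and 312, at 3.33%, 4.55%, 4.52% and 5.15% of cells. Transcripts of the erythroid list, most of whose members are haemoglobin genes, in B cells were at 2230, 45.0, 359 and 653 CPM and in T cells at 612, 510, 55.6 and 48.2 CPM, so that they did not keep the same ratio between these classes in the different libraries.

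mt-Nd3 was at 1942, 1197, 2.09 and 811 CPM in T cells, and its nuclear copy Gm28438 at 1.96, 1.24, 618 and 0.75 CPM. Gm28438 also reached 740 CPM in B cells and 261 CPM in monocytes or macrophages of TAA+C7.5. Slc15a2 was at 73.7, 0, 40.1 and 29.5 CPM in T cells, at 98.0, 0.201, 84.2 and 66.7 CPM in B cells, and at 41.6, 33.9, 45.6 and 67.6 CPM in cholangiocytes.

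Lists added later were measured in the same classes. For TAA+C7.5 against TAA the glucocorticoid list was at 0.16 in T cells, 0.30 in B cells, 0.20 in monocytes or macrophages, -0.01 in neutrophils and 0.14 in NK or ILC. Evening minus morning clock genes were at -0.21 (-0.39 to 0.04) in T cells, 0.01 (-0.25 to 0.21) in B cells, -0.45 (-0.68 to -0.14) in monocytes or macrophages, -0.40 (-0.90 to 0.13) in neutrophils and -0.04 (-0.64 to 0.47) in NK or ILC.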
